A study of Homo sapiens with 12 samples.

How the data were processed

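The deposited data are a table of raw counts per gene symbol for the 12 libraries of RD cells, which the authors gave without normalization. Per the labels, 500000 cells were seeded, left to attach for 24 h and grown with or without 10 ng/mL doxycycline for 96 h. Stranded mRNA libraries were sequenced as 75-base paired-end reads on an Illumina NextSeq instrument. The submitters' processing notes name Trim Galore 0.6.4, STAR 2.7.3a, featureCounts, Subread 1.6.3 and the GRCh38 build, with no roles or order. The gene annotation behind the counts is not given in the sources used here. The table ends with 5 special rows named in the style of HTSeq-count for reads that were not assigned to a gene, which were kept out of the fits and used only as a check. Groups came from the sample titles and the table's column headers, which give matching treatments and replicate numbers. The headers name NT5E, the gene of CD73, where the titles name CD73. They number the constructs Sh1 and Sh2, and Sh1 was taken as the construct titled ish, the only other one being ish2.

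The table holds 26485 gene symbols. Of these, 23925 were current in the reference tables, 1459 matched as older symbols or synonyms and 1101 did not match; of 874 gene list entries, 857 matched, 45 of them through an older symbol. Gene positions are from the GENCODE annotation of GRCh38, the build named by the submitters. Gene counts per library ran from 26566603 to 32692207. The common dispersion was 0.000596, a biological coefficient of variation of 2.44%, so small folds pass the test. Counting noise alone did not account for the spread: the chi-square per degree of freedom between replicates was 1.40 to 4.89, so no library was a copy of another.

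Genes were filtered by filterByExpr by group, which kept 15206 and left out 11279, and scaled by TMM. One quasi-likelihood fit of 4 group means (edgeR 4.0.16, glmQLFit with robust spread, in R 4.3.3 with limma 3.58.1) gave 5 contrasts: Dox against no Dox in ish, the same in ish2, their mean, the ish2 effect minus the ish effect, and ish2 against ish without Dox. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Fold changes are Dox over no Dox, and CPM are read counts scaled to library size with TMM factors. SE is the absolute log2 fold change divided by the square root of the quasi-likelihood F. It is back-calculated from the test, so it only approximates a standard error and may be too small for large changes. The replicate numbers did not pair the samples (correlations of residuals between like numbers were -0.0798 to 0.0381, and 3 of 12 libraries went best with their own number), so no pairing entered the fit. NT5E was also tested by an exact two-sided permutation of log2 CPM. The overlap of calls used Fisher's exact test with the tested genes as background.

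Of 28 gene lists written before the data were examined, 27 were tested, and the mitochondrially encoded genes were not analysed here. The lists share 8 tested genes. Each was tested with camera on log2 CPM (prior count 2) at the preset correlation of 0.01, and again with an estimated correlation and with fry, adjusting over the lists. Estimating the correlation also lowers the degrees of freedom of camera, so a call lost there need not reflect correlation between genes. Camera compares a list with all other genes, whereas fry asks whether the list's genes move one way. Members rose or fell by the edgeR call over all tested genes, and counts adjusted over the list alone are given beside them. Genes are named by a rule fixed before the data were examined. It takes NT5E; per construct the 10 largest rises and 10 largest falls with an official symbol, a mean log2 CPM of at least 1 in the higher group and no overlap between groups; 12 each way for the common effect by the smaller of both changes; 5 each way for the difference and for the lines without Dox; up to 4 members per list with the smallest p; all members of the nucleotide enzyme and receptor lists; and PAX7, MYOD1, MYOG, MYH3, CDKN1A and MKI67. With Dox at 3 libraries against 3, 10% of genes would show no overlap by chance alone. Of the genes so chosen, those with a few reads in the lower group are not described, and the results of a few others are not reported here.

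The fit was tested on simulated data with planted changes. Of genes planted at 1.25-fold, 1.5-fold and 2-fold, 68.2%, 83.1% and 93.8% were called in the ish contrast, with 7 unchanged genes called among 15009 tested. The same shares were 55.2%, 81.8% and 90.9% in ish2 (20 unchanged called), 57.9%, 81.7% and 87.8% for the mean effect (22), 53.4%, 79.4% and 87.8% for the difference (15), and 68.7%, 90.9% and 93.8% without Dox (10). For the mean and the difference, each change was planted in 1 construct only. A change common to both was not simulated, and the planted change in the mean was smaller than the fold named. Few genes were changed in the simulation (196 tested in ish), whereas 11945 were called in ish in the real data. These shares may therefore not carry over. The camera test called the 1 planted list and 0 of 20 unchanged lists. The simulated genes were drawn independently of each other. This check therefore does not cover lists whose genes vary together, such as the S phase list (estimated correlation 0.702).

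Alternatives were RLE size factors, library size alone, no low-count filter, a CPM of at least 1 in at least 3 libraries, DESeq2 1.42.0, limma-voom, a replicate block, each construct's own 6 libraries, a stricter adjusted p of 0.01, a 2-fold minimum and each library left out in turn. Leaving out 2 libraries together was added after the data were seen. For the scan of 3' UTR words, the presence of each of 16220 7-mers in the longest 3' UTR of 11239 genes was related to the fold changes, with UTR length and base and dinucleotide content as covariates, in Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and the values were set against 100 permutations of the fold changes; a planted word was recovered at rank 1 on simulated data. Splice forms, proteins and adenosine were not analysed here.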

Results

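RNA was sequenced from RD cells, an established human line from a fusion-negative rhabdomyosarcoma, a soft-tissue tumour whose cells carry features of developing skeletal muscle. The cells held a doxycycline-inducible hairpin against NT5E, the gene for CD73, a cell-surface enzyme that makes adenosine from extracellular AMP. There were 2 constructs, titled ish and ish2, and the column headers of the deposited table number both as hairpins against NT5E. Their sequences, and any further difference between them, are not given in the sources used here. Each construct was grown with 10 ng/mL doxycycline (Dox) or without it for 96 h, with 3 libraries per group and 12 in all. The gene counts per library ran from 30137434 to 31926254 for ish without Dox, from 30250071 to 32692207 for ish with Dox, from 26566603 to 27789289 for ish2 without Dox and from 26957197 to 31249928 for ish2 with Dox. Nothing in the labels says that the replicates are separate cultures, so the p-values below measure the spread between samples, which may be technical. No sample combined Dox with a non-targeting hairpin, so each Dox effect holds the drug, the hairpin machinery and the loss of NT5E together.

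The first question was how far NT5E mRNA fell. In ish, NT5E went from 16.7 ± 1.61 CPM (normalised read count, scaled to library size; mean ± SD, n = 3) to 1.57 ± 0.354 with Dox, a 10.7-fold fall (log2 fold change -3.41, SE 0.11, edgeR adjusted p = 3.31e-25). In ish2 it went from 23.2 ± 1.03 to 14.6 ± 0.542 CPM, a 1.59-fold fall (log2 fold change -0.67, SE 0.07, adjusted p = 4.62e-11). The effects differed by 2.74 on the log2 scale (adjusted p = 2.91e-19), so NT5E mRNA with Dox was lower in ish than in ish2. All 3 Dox libraries lay below all 3 libraries without Dox in each construct, and the exact two-sided permutation p of 0.1 is the smallest that 3 against 3 can give. NT5E lies on chromosome 6 of GRCh38, from 85449584 to 85495791 on the plus strand, and its reference mRNA has 8 exons and 3918 bases.

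**Figure D1:**
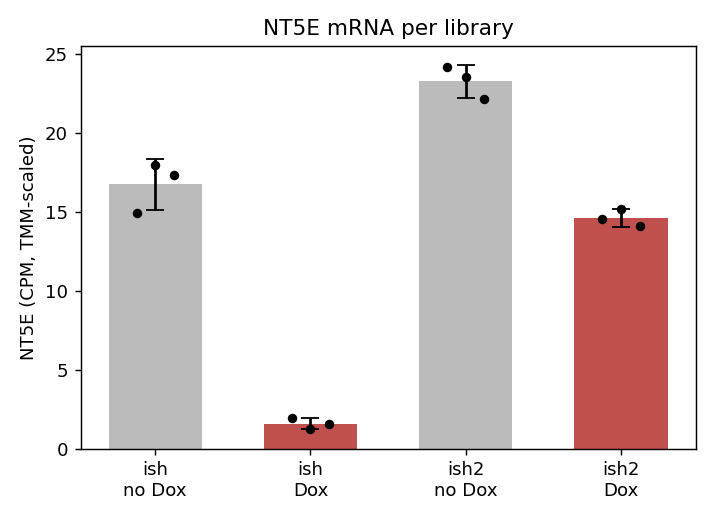
NT5E mRNA in CPM (normalised read count, TMM-scaled) in the 4 groups; bars are means, whiskers are SD, and each point is 1 of 3 libraries. The mean fell from 16.7 to 1.57 CPM in ish and from 23.2 to 14.6 CPM in ish2.

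In ish, 50 of 52 contractile genes of muscle rose with Dox, and all 36 mitosis genes, 22 of 24 RAS and MAPK output genes and 13 of 19 inflammatory genes fell. As lists, these 4 were called at the preset correlation but not with an estimated one (adjusted p = 0.228 for contractile, RAS and MAPK and inflammatory genes and adjusted p = 0.271 for mitosis). MYOG, the transcription factor of terminal muscle differentiation, rose 6.17-fold (log2 fold change 2.62, SE 0.07, n = 3 against 3), from 106.2 ± 3.82 to 654.4 ± 16.1 CPM. MYH3, the embryonic myosin heavy chain, rose 9.69-fold (log2 fold change 3.28, SE 0.05), and CDKN1A, which encodes the cell-cycle inhibitor p21, rose 4.32-fold (log2 fold change 2.11, SE 0.07). CCL2, a chemokine that attracts monocytes, fell from 120.9 ± 1.82 to 0.996 ± 0.193 CPM (log2 fold change -6.91, SE 0.10), and ETV4, an ETS transcription factor downstream of ERK, fell 14.5-fold (log2 fold change -3.86, SE 0.05). On GRCh38, MYOG lies on chromosome 1 (203083132 to 203086036), MYH3 on chromosome 17 (10628526 to 10657309), CDKN1A on chromosome 6 (36676460 to 36687339) and CCL2 on chromosome 17 (34255218 to 34257203).

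Of the 52 tested genes of the contractile and sarcomere list in ish, 50 rose and 1 fell, with a median log2 fold change of 2.42. The camera test against all other genes gave an adjusted p of 2.78e-15, and adjusted p = 0.228 with an estimated correlation. Its risers included ACTN2, the Z-disc actinin (3.41), TNNT2, the cardiac and embryonic troponin T (3.90), MYL4, the embryonic light chain (3.53), and UNC45B, a myosin chaperone (3.12). Among the 30 myogenic regulators, 18 rose and 9 fell (camera adjusted p = 0.0739). MYOD1, the muscle-determining factor, rose by 1.596 and MEF2C, its partner in differentiation, by 2.93, whereas FGFR4, a growth factor receptor of muscle progenitors, fell by 1.02. TMEM8C, the older symbol of the myoblast fusion gene myomaker, rose by 2.55, and PAX7, a marker of muscle stem cells, had a log2 fold change of -0.003 that was not called (adjusted p = 0.929).

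All 36 mitosis and G2/M genes fell in ish (median -1.05, camera adjusted p = 3.53e-13, adjusted p = 0.271 with an estimated correlation). TOP2A, the topoisomerase of dividing cells, fell by 1.52, CCNB2, a mitotic cyclin, by 1.80, and MKI67, which encodes the proliferation marker Ki-67, by 0.93. Of the 35 DNA replication and S phase genes, 29 fell and 2 rose (median -0.305, camera adjusted p = 0.00133, adjusted p = 0.553 with an estimated correlation), with falls of 1.37 for the replication factor GINS2 and 0.94 for the licensing factor CDT1. Of the 24 RAS and MAPK output genes, 22 fell and 1 rose (median -1.44, camera adjusted p = 2.4e-08, adjusted p = 0.228 with an estimated correlation). DUSP6, the ERK phosphatase induced by ERK itself, fell by 2.95, and ETV1 and HMGA2 fell by 1.47 and 1.62.

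Of the 19 NF-kB and inflammatory genes in ish, 13 fell and 3 rose (median -1.14, camera adjusted p = 0.021, adjusted p = 0.228 with an estimated correlation). CXCL8, the neutrophil chemokine, fell by 4.28, and ICAM1, an adhesion molecule, by 2.82. Interferon stimulated genes fell at 22 of 35 and rose at 8 (median -0.557, camera adjusted p = 0.00623, adjusted p = 0.41 with an estimated correlation), IFIT1 by 2.32 and IFIT2 by 1.75. Glycolysis and hypoxia genes fell at 25 of 35 and rose at 7 (median -0.549, camera adjusted p = 0.00589, adjusted p = 0.485 with an estimated correlation), including the glucose transporter SLC2A3 (-1.74) and the glycolytic regulator PFKFB3 (-2.13). Genes of ATF4 and the integrated stress response fell at 22 of 33 and rose at 6 (median -0.574, camera adjusted p = 0.0166, adjusted p = 0.63 with an estimated correlation), with a fall of 2.11 for DDIT4, an mTOR inhibitor.

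Cholesterol biosynthesis genes rose at 19 of 25 and fell at 2 in ish (median 0.741, camera adjusted p = 9.31e-05, adjusted p = 0.41 with an estimated correlation), among them LSS (1.24) and SQLE (1.00). Nuclear encoded respiratory chain genes rose at 43 of 54 and fell at 7 (median 0.383, camera adjusted p = 1.65e-06, adjusted p = 0.41 with an estimated correlation), with NDUFA10 of complex I at 0.74. Cytosolic ribosomal protein genes rose at 58 of 69 and fell at 4 (median 0.265, camera adjusted p = 2.4e-08), and mitochondrial ribosomal protein genes rose at 43 of 72 and fell at 14 (median 0.178, camera adjusted p = 0.00677), each with an adjusted p = 0.41 with an estimated correlation. The adenosine and P2 receptors rose at 7 of 9 with none called lower (median 0.493, camera adjusted p = 0.039, adjusted p = 0.228 with an estimated correlation of -0.00287, below the preset one), including the adenosine receptor ADORA1 (1.09) and the ATP-gated channel P2RX5 (0.98). That last call was lost without ish Dox replicate 1 (adjusted p = 0.055) and without the low-count filter (0.221; range over the camera alternatives 0.0276 to 0.228). Of the 9 endothelial markers tested, 7 fell and 1 rose (median -1.40, camera adjusted p = 0.0303, adjusted p = 0.228 with an estimated correlation of -0.0576, below the preset one), with falls of 2.10 for TEK and 0.95 for ENG. The endothelial call was also lost when ish was fitted from its own 6 libraries (adjusted p = 0.0586, range over the camera alternatives 0.0157 to 0.228).

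The fit called 11945 of 15206 tested genes in ish, of which 5941 rose and 6004 fell, and 2701 of them passed 2-fold (1107 higher, 1594 lower). Outside the lists, the largest risers with enough reads were PGM5, a phosphoglucomutase relative found at adhesion sites (log2 fold change 6.34, SE 0.11), and ABLIM3, an actin-binding LIM protein (6.02, SE 0.09). The netrin receptor UNC5D (-4.87, SE 0.11), the neuropeptide precursor VGF (-4.52, SE 0.22) and the cytokine receptor IL27RA (-4.19, SE 0.13) were among the largest falls. Adjusted over the list alone, the counts were the same for each list above except the interferon genes (8 rose, 23 fell) and the receptors (7 rose, 1 fell). No splice forms were measured, and reads from near-identical paralogs such as the myosin heavy chains MYH3 and MYH8 may have been set aside as not unique.

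In ish2, 39 of the 52 contractile genes fell with Dox and 6 rose, while 17 of 18 cAMP genes, 17 of 19 inflammatory genes and 30 of 35 interferon genes rose. With an estimated correlation the cAMP list kept its call (adjusted p = 0.00907), whereas the contractile (adjusted p = 0.385), inflammatory (adjusted p = 0.0631) and interferon lists (adjusted p = 0.142) did not. MYOG fell 4.73-fold (log2 fold change -2.24, SE 0.10, n = 3 against 3), from 82.9 ± 10.3 to 17.6 ± 1.03 CPM, and MYH3 fell 2.31-fold (-1.21, SE 0.07). SEMA7A, a membrane-anchored semaphorin, rose 8.03-fold (log2 fold change 3.01, SE 0.05), from 19.8 ± 2.51 to 158.6 ± 1.94 CPM, and SOX9, a transcription factor of cartilage and progenitor cells, rose 6.70-fold (2.74, SE 0.06). GTF3A, which encodes the transcription factor of 5S ribosomal RNA genes, fell 6.46-fold (log2 fold change -2.69, SE 0.06). On GRCh38, SEMA7A lies on chromosome 15 (74409289 to 74433958) and GTF3A on chromosome 13 (27424544 to 27435823).

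Of the 18 cAMP and CREB responsive genes, 17 rose in ish2 and none was called lower (median 0.814, camera adjusted p = 1.57e-07). This was the one list call in ish2 that held with an estimated correlation (adjusted p = 0.00907). IRS2, an insulin receptor substrate, rose by 1.94, the circadian repressor BHLHE40 by 1.16, CREM, a cAMP-responsive transcription factor, by 0.98, and RGS2, a regulator of G-protein signalling, by 0.86. Interferon stimulated genes rose at 30 of 35 and fell at 2 (median 0.595, camera adjusted p = 1.72e-08, adjusted p = 0.142 with an estimated correlation), with OASL at 1.37, IFIT2 at 1.42 and OAS3 at 1.12. NF-kB and inflammatory genes rose at 17 of 19 with none lower (median 0.708, camera adjusted p = 0.000154, adjusted p = 0.0631 with an estimated correlation), including the T-cell chemokine CCL5 (2.34), RELB (1.20) and ICAM1 (1.16).

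RAS and MAPK output genes rose at 18 of 24 and fell at 4 in ish2 (median 0.38, camera adjusted p = 0.000765, adjusted p = 0.486 with an estimated correlation), with DUSP5 at 1.77, IER3 at 1.05 and DUSP6 at 0.27. Unfolded protein response genes rose at 16 of 21 and fell at 1 (median 0.25, camera adjusted p = 0.00164, adjusted p = 0.431 with an estimated correlation), among them the chaperones DNAJB9 (1.05) and HYOU1 (0.35). Glycolysis and hypoxia genes rose at 17 of 35 and fell at 4 (median 0.159, camera adjusted p = 0.00832, adjusted p = 0.67 with an estimated correlation), SLC2A3 by 1.68 and PFKFB3 by 1.36.

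Contractile and sarcomere genes fell at 39 of 52 and rose at 6 in ish2 (median -0.758, camera adjusted p = 1.7e-07, adjusted p = 0.385 with an estimated correlation). ATP2A1, the calcium pump of fast muscle, fell by 2.28 and MYBPH, a myosin-binding protein, by 2.29, whereas DES, which encodes desmin, rose by 0.65. Mitosis genes fell at 32 of 36 (median -0.401, camera adjusted p = 1.56e-09, adjusted p = 0.431 with an estimated correlation), and S phase genes at 33 of 35 (median -0.472, camera adjusted p = 1.13e-08, adjusted p = 0.517 with an estimated correlation). MKI67 fell by 1.17, the spindle protein NUSAP1 by 1.04 and E2F2, a cell-cycle transcription factor, by 1.32. CDKN1A rose by 0.51 and PAX7 fell by 0.91. Respiratory chain genes fell at 23 of 54 and rose at 8 (median -0.04, camera adjusted p = 0.0374, adjusted p = 0.78 with an estimated correlation), a call lost without ish2 Dox replicate 3 (adjusted p = 0.0565) or ish2 no-Dox replicate 3 (0.102; range over the camera alternatives 0.00486 to 0.78).

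The fit called 9883 genes in ish2, 5150 higher and 4733 lower, and 933 of them passed 2-fold (590 higher, 343 lower). Other large risers were the complement receptor C3AR1 (2.90, SE 0.10), the hyaluronan synthase HAS3 (2.81, SE 0.10) and the vitamin D hydroxylase CYP24A1 (3.16, SE 0.19). NOTUM, a secreted WNT inhibitor (-2.51, SE 0.09), and ATOH8, a helix-loop-helix factor (-2.48, SE 0.11), were among the largest falls. Adjusted over the list alone, the counts of the 10 lists with a camera call in ish2 were the same as over all genes tested.

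The next comparison asked what the constructs had in common, as the mean of both Dox effects. What fell in both was the machinery of cell division: all 36 mitosis genes fell in the mean effect (median -0.711, camera adjusted p = 9.59e-15), 32 of them in both constructs, and all 35 S phase genes fell (median -0.403, camera adjusted p = 5.8e-08), 27 of them in both. With an estimated correlation the adjusted p was 0.597 for mitosis and 0.641 for S phase genes. NUSAP1 fell by 1.23 in ish and 1.04 in ish2, and CDT1 by 0.94 and 0.95. TRIL, a co-receptor of Toll-like receptors, fell 9.23-fold in ish and 2.40-fold in ish2, LEFTY1, an inhibitor of NODAL signalling, 3.67-fold and 6.79-fold, and FBLN5, an elastic fibre protein, 4.53-fold and 2.37-fold. KLF2, a zinc-finger transcription factor, rose 2.37-fold (log2 fold change 1.24, SE 0.06) and 2.38-fold (1.253, SE 0.05), and the translation factor EIF5A2 rose 2.62-fold and 2.31-fold.

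Genes that rose in both constructs included GOLGA7B (12.2-fold in ish and 3.83-fold in ish2), the protocadherin PCDH9 (3.46-fold and 5.82-fold), the RNA-binding protein gene ELAVL2 (3.16-fold and 2.57-fold) and GCH1, the first enzyme of tetrahydrobiopterin synthesis (2.72-fold and 2.41-fold). COL9A3 (7.33-fold and 3.95-fold), DRAXIN (3.71-fold and 4.09-fold), a repellent of growing axons, and MYT1 (4.44-fold and 2.62-fold), a neural zinc-finger factor, fell in both. Cholesterol biosynthesis genes rose at 19 of 25 and fell at 3 in the mean effect (median 0.545, camera adjusted p = 0.000134, adjusted p = 0.641 with an estimated correlation), and 13 rose in both constructs, with CYP51A1, the lanosterol demethylase, at 0.54 and 0.29.

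The mean effect called 11300 genes, 5628 higher and 5672 lower, and 858 passed 2-fold. For several lists it averaged opposite effects: contractile genes (41 rose, 5 fell; camera adjusted p = 3.6e-08) and RAS and MAPK output genes (3 rose, 20 fell; 0.000114) each had an adjusted p = 0.597 with an estimated correlation, and took their sign from ish. The respiratory chain (35 rose, 8 fell, camera adjusted p = 0.00229), the cytosolic ribosomal proteins (53 rose, 9 fell, 8.85e-05) and the mitochondrial ribosomal proteins (43 rose, 16 fell, 0.0249) were also called, all with an adjusted p = 0.641 with an estimated correlation. Of members called in both constructs, 20 of 30 respiratory chain, 14 of 31 cytosolic and 8 of 36 mitochondrial ribosomal genes rose in ish and fell in ish2. The reverse held for 1, 0 and 4. ATF4 and integrated stress response genes fell at 21 of 33 and rose at 5 (camera adjusted p = 0.0249, adjusted p = 0.725 with an estimated correlation), a call lost without ish2 Dox replicate 1 (adjusted p = 0.0527; range over the camera alternatives 0.000676 to 0.725). Adjusted over the list alone, 42 contractile genes rose and 5 fell, and 6 ATF4 genes rose and 21 fell, with no change for the other lists named for this effect.

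**Figure D2:**
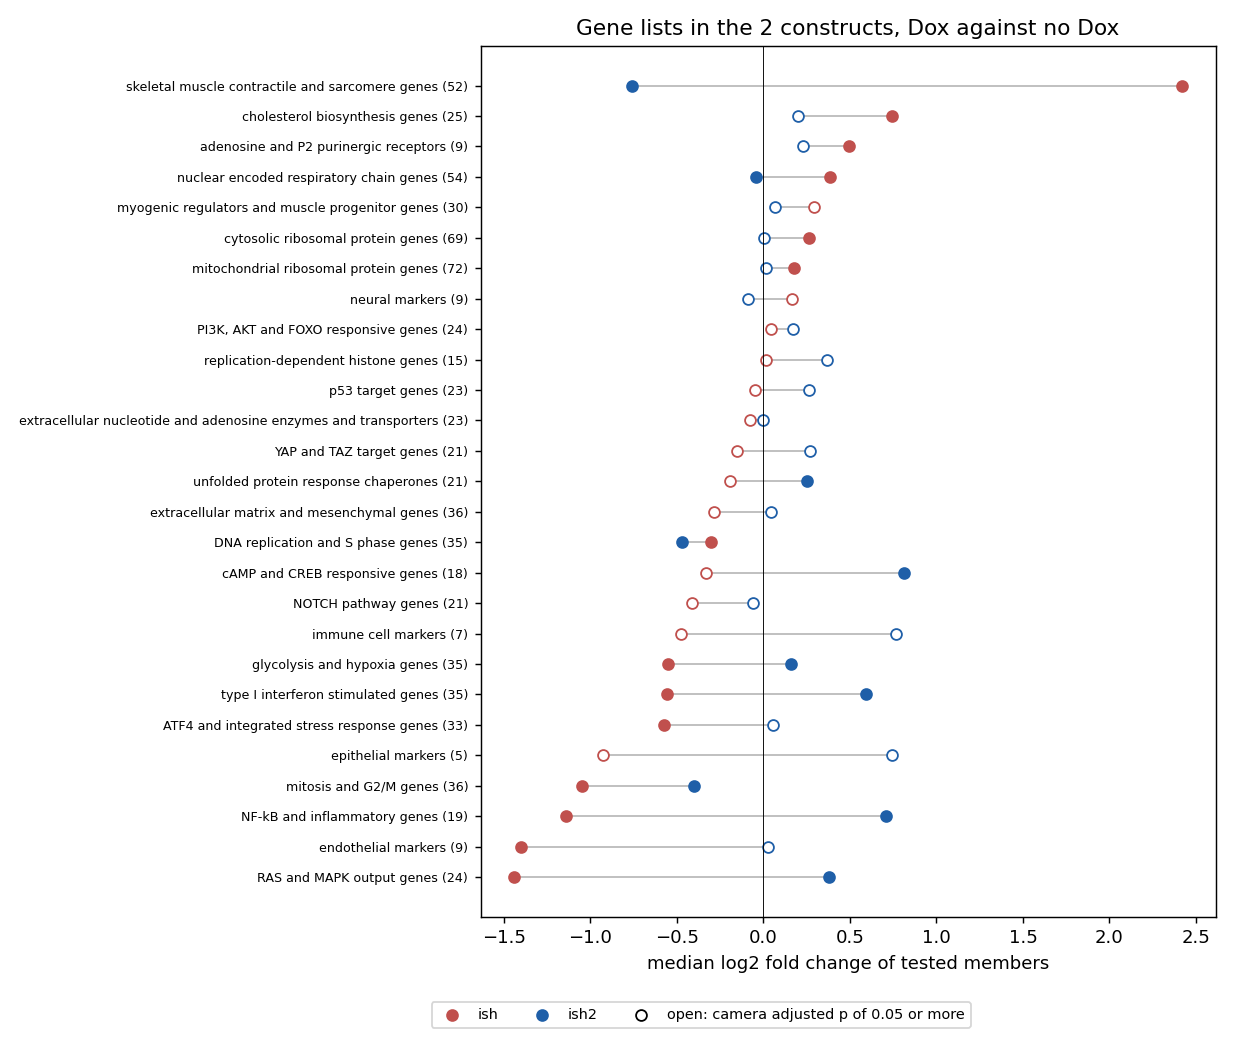
Median log2 fold change (Dox against no Dox) of the tested members of each gene list in ish and ish2, with the number of members in brackets; a filled point has a camera adjusted p under 0.05 with the preset correlation. Contractile genes lay at 2.42 in ish and -0.758 in ish2, and mitosis genes at -1.05 and -0.401.

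The responses of the constructs were then compared with each other to see which changes they shared. CCL2 fell in ish and rose 1.17-fold in ish2 (difference of log2 fold changes 7.14). EMP1, a membrane protein, fell 12.6-fold in ish (log2 fold change -3.655, SE 0.13) and rose 3.37-fold in ish2 (1.75, SE 0.10, n = 3 against 3). In the opposite sense, the perinatal myosin MYH8 rose 11.97-fold in ish and fell 3.51-fold in ish2, and TNNT2 rose 14.96-fold and fell 2.03-fold. MYOG rose in ish and fell in ish2 (adjusted p of the difference 7.48e-11).

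By lists, 39 contractile genes rose in ish and fell in ish2, and none went the other way (median difference -3.2, camera adjusted p = 9.95e-17, adjusted p = 0.103 with an estimated correlation). The opposite held for 20 interferon genes (median difference 1.14, camera adjusted p = 5.77e-08, adjusted p = 0.129 with an estimated correlation), with IFIT2 and IFIT3 lower in ish and higher in ish2, and for 16 RAS and MAPK output genes (1.84, camera adjusted p = 2.8e-09, adjusted p = 0.136 with an estimated correlation), such as EGR1 at -1.47 and 0.66. It also held for 12 NF-kB genes (2.03, camera adjusted p = 0.000186, adjusted p = 0.073 with an estimated correlation) and for 11 cAMP genes (1.13, camera adjusted p = 2.96e-05), where the call held with an estimated correlation (adjusted p = 0.0377). Mitosis genes fell further in ish than in ish2 at 34 of 36 (0.646, camera adjusted p = 5.77e-08, adjusted p = 0.332 with an estimated correlation). Adjusted over the list alone, the counts of differing genes were the same for the contractile, interferon, RAS and MAPK, NF-kB and cAMP lists, and for mitosis 34 were higher and 2 lower.

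The effects differed at 11039 genes, with the more positive effect in ish2 at 5688 and in ish at 5351, and at 3247 by at least 1 on the log2 scale. Of the genes called in both constructs, 4249 moved the same way and 3971 (48.3%) moved oppositely. Over all calls, 2149 genes fell in both against 1869 from chance (Fisher's exact p = 1.7e-23), 2100 rose in both against 2012 (p = 0.00212), 2140 fell in ish and rose in ish2 against 2033 (p = 0.000202), and 1831 rose in ish and fell in ish2 against 1849 (p = 0.518). Among genes past 2-fold in both, 135 moved the same way and 284 oppositely. In that set, 87 rose in both against 42.9 from chance (Fisher's exact p = 2.2e-10), 48 fell in both against 35.96 (p = 0.0397), 181 fell in ish and rose in ish2 against 61.9 (p = 2.49e-43), and 103 rose in ish and fell in ish2 against 25.0 (p = 2.38e-37). Fisher's test takes genes as independent units, which co-regulated genes are not. Every count past 2-fold exceeded chance, also those in the same direction, so these p-values alone do not measure opposition. Across the 15206 genes, which are not independent replicates, Pearson's r of the fold changes was -0.102 and Spearman's rho -0.013, and r stayed between -0.111 and -0.0399 in every setting tried.

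**Figure D3:**
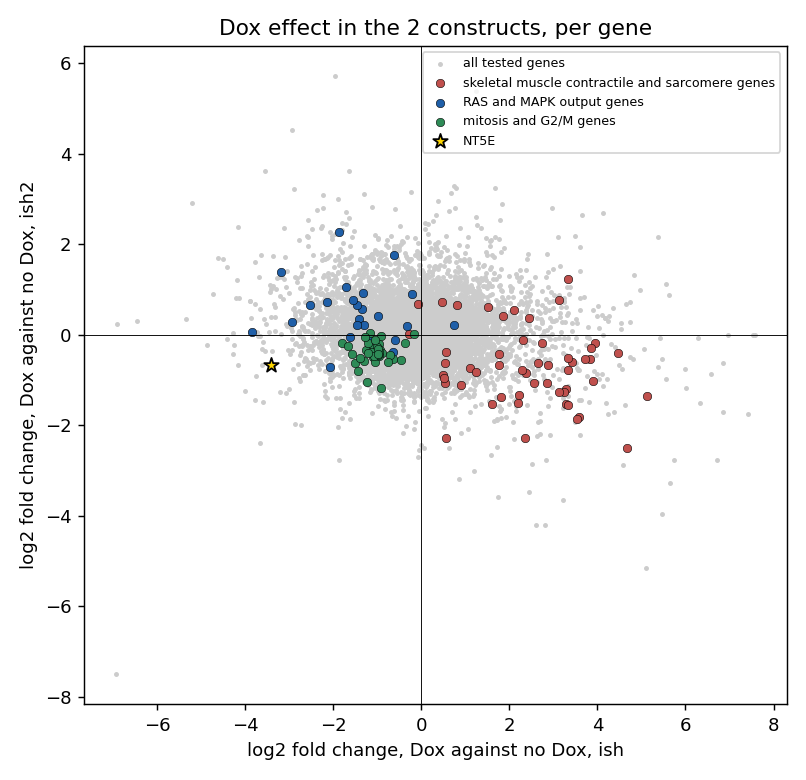
Log2 fold change with Dox in ish (horizontal) and ish2 (vertical), 1 point per tested gene; contractile genes are red, RAS and MAPK output genes blue, mitosis genes green, and NT5E is the star. Contractile genes lie mostly at the lower right (39 rose in ish and fell in ish2), mitosis genes at the lower left (32 fell in both), and NT5E at -3.41 and -0.67.

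The last comparison set the constructs side by side without Dox, to see how alike the lines were before induction. They differed at 3974 genes, 2088 higher in ish2 and 1886 lower, but at 64 by at least 1 on the log2 scale, 15 of them higher and 49 lower. The balance over all calls depended on the scaling, with 1810 higher and 2115 lower with library size alone and 2426 higher and 1668 lower with RLE size factors. The carbonic anhydrase CA9, a hypoxia marker, was lower in ish2 (log2 difference -2.25, SE 0.46; 3.04 ± 1.09 CPM in ish and 0.63 ± 0.33 in ish2, n = 3 each), as was MIR210HG, the host gene of a hypoxia-induced microRNA (-1.10, SE 0.15). PAPPA, a protease of IGF-binding proteins, was higher in ish2 (0.94, SE 0.06), as were the stress gene CHAC1 (0.85, SE 0.06) and GALNT15 (0.98, SE 0.13). NT5E was higher in ish2 by 0.47. The count fell to 2508 when ish no-Dox replicate 3 and ish2 no-Dox replicate 3 were left out together, a check added after the data were seen. The first had 9.571% of its reads not aligned uniquely, against 7.518% and 7.677% in its group. The second lay apart from its group on the third principal component (-18.91 against -10.53 and -12.11).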

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

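The tests of a weaker shared response and of the RAS and MAPK cascade genes were chosen only after the result was seen; the 7-mer scan, the length and GC check and the regroupings of samples were planned.

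The constructs differed in their response to Dox at 11039 genes, by a test of the difference itself, and in the contractile, interferon, NF-kB and RAS output lists most members called in both moved in opposite directions, although these list differences were not called with an estimated correlation (adjusted p = 0.103, 0.129, 0.073 and 0.136). A weaker copy of the ish response in ish2, where NT5E fell less, was argued against: 48.3% of the genes called in both moved oppositely. Transcript length and GC content explained at most 3.76% of the variance of the fold changes (ish2; 0.898% in ish), which excludes them as the whole cause. What stays open is that each hairpin may silence other transcripts through its seed: the 7-mer whose presence in 3' UTRs went with the largest fall occurs in NT5E mRNA in both constructs, as do 20.2% of all 7-mers scanned (34.8% on either strand), with t = -13.79 in ish (lowest of 100 permutations -5.11) and -9.62 in ish2 (lowest -4.83). A graded effect of CD73 loss that turns direction was not tested, since each construct had 1 depth of knockdown, and separate histories of the lines stay open too, although without Dox they differed by at least 1 (log2) at 64 genes against 3247 for the responses.

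RAS and MAPK output genes differed by a median of 1.84 (ish2 minus ish), and fell in ish at 22 of 24. Of 40 scanned genes listed for the RAS and MAPK cascades, those that moved by at least 1 in ish went both ways. MAP2K1 fell by 2.38, NRAS, the RAS gene known to be mutated in RD cells, by 1.97, and RPS6KA1 by 1.83. RRAS fell by 1.77, SHC1 by 1.52, RPS6KA3 by 1.19, PDGFRB by 1.18 and FGFR4 by 1.02, whereas MRAS rose by 3.254 and MAP2K5 by 1.29. Of these 10, NRAS and RPS6KA3 hold a 3' UTR match to a leading ish 7-mer. Over all 40, the median log2 fold change in ish was -0.424 in the 13 with a match and -0.046 in the 27 without (difference -0.379, permutation p = 0.1788). The words were chosen from these same ish fold changes, so a lower median with a match was likely in advance. Over all scanned genes the median was -0.186 with a match and 0.034 without. With so few genes the comparison does not settle whether the matched cascade genes fell further, and it does not bear on CD73. No sample combined Dox with a non-targeting hairpin. Seed-matched silencing of the cascade, a loss of RAS output through CD73 and other effects of Dox therefore cannot be told apart.

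The other results below were taken up because a test of the difference between constructs called them, and they are given as values (ish2 minus ish, log2). NT5E differed by 2.74, with the deeper fall in ish. Among single genes, the difference was 7.14 for CCL2, 6.18 for VGF, 5.91 for KIAA0226L and 5.41 for EMP1, and it was -5.395 for both MYH8 and MYL4, -5.30 for ARPP21, -5.29 for DCLK1, a kinase of the microtubule skeleton, and -4.925 for TNNT2. Of 284 other named genes, 251 differed between the constructs, against 11039 of all 15206 tested genes. Most were named for large changes or small p-values, so a high share was built in. The median difference over list members was -3.2 for contractile genes, 2.03 for NF-kB genes, 1.14 for interferon genes and 1.13 for cAMP genes. It was 1.88 for 5 epithelial markers and 1.62 for 9 endothelial markers, 0.75 for glycolysis and hypoxia genes, 0.693 for the unfolded protein response, 0.646 for mitosis genes and 0.5 for ATF4 genes. It was -0.479 for the respiratory chain, -0.469 for myogenic regulators, -0.454 for cholesterol synthesis, -0.26 for cytosolic and -0.154 for mitochondrial ribosomal proteins. With an estimated correlation the cAMP difference alone kept its call among these 16 lists. The epithelial call was lost with 10 of the 12 libraries left out in turn (adjusted p of 0.0333 to 0.115 over the 12), with library size alone (0.0506) and without the low-count filter (0.301). The ATF4 call was lost without replicate 3 of ish2 with Dox (0.058) or without Dox (0.0546; range over the camera alternatives 0.00978 to 0.7), and the mitochondrial ribosomal call without ish2 Dox replicate 3 (0.0524; range over the same 0.0158 to 0.46).

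Outside the gene counts, the share of reads that fell in no annotated feature was 12.75 ± 0.111% in ish with Dox against 11.82 ± 0.218% without (n = 3 each, exact permutation p = 0.1, the smallest possible), and it went the other way in ish2 (10.89 ± 0.168% against 11.66 ± 0.223%). The share that matched more than 1 feature was lower with Dox in both, at 2.083 ± 0.012% against 2.626 ± 0.0296% in ish and 2.355 ± 0.019% against 2.575 ± 0.00553% in ish2, as was the share not aligned (0.6496% against 0.7062% and 0.6185% against 0.6705%), each with the same exact p = 0.1.

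For the counts of called genes, the real split of 3 against 3 gave 11945 in ish, 9883 in ish2 and 3974 without Dox, and the highest of the other splits gave 0 in each, but 10 splits are too few for a share under 0.05. For the mean effect and the difference, 100 of 200 splits within constructs were drawn, and only the real one (1 of 100) reached 11300 and 11039 genes, with 7306 as the highest other for each. That share is under 0.05, but each other split drawn mixed libraries with and without Dox in at least 1 construct. Such mixing widens the spread within groups and lowers the count, so no conclusion is drawn from the share. The split that exchanges Dox and no Dox in 1 construct was not among those drawn, and by construction it turns each of these counts into the other. For the difference it would give 11300, above the real 11039.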

How the results depend on the processing

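Leaving out 2 libraries together was chosen only after the data were seen; all other alternatives were planned before the data were examined. Libraries held at least 26566603 gene counts, 15206 of 26485 genes had enough reads to be tested, and no other effect of depth was examined. No named gene with a call turned direction among 608 results in the settings run, and the counts stayed within 1.5 times of their values except where given here. Leaving out 1 library gave 11544 to 12140 genes in ish, 9350 to 9893 in ish2, 11039 to 11249 for the mean effect, 10807 to 10977 for the difference and 2985 to 4099 without Dox. NT5E then lay between -3.59 and -3.28 in ish and between -0.72 and -0.66 in ish2. A replicate block over all libraries gave 11926, 9835, 11267, 11017 and 3918, though the numbers do not pair the samples. A 2-fold minimum left 2701 genes in ish, 933 in ish2, 858 for the mean, 3247 for the difference and 64 without Dox, by its construction. An adjusted p of 0.01 left 2502 genes without Dox, and leaving out ish no-Dox replicate 3 and ish2 no-Dox replicate 3 left 2508 there, with fewer samples. The gene list calls depended most on the test: 14, 10, 9 and 16 lists were called in ish, ish2, the mean and the difference at the preset correlation, 0, 1, 0 and 1 with an estimated correlation, and 26, 21, 26 and 25 with fry, which does not compare a list with other genes. The NF-kB list had no call in the mean effect with camera (up, adjusted p = 0.97; highest over its camera alternatives 0.995) and went down with fry (adjusted p = 0.000786), where the mean of its members was -0.338 and the median 7.3e-05. With library size alone or RLE factors the median fold change moved by at most 0.0236.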

Other observations

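The follow-ups of the 7-mers in the other construct, the shares of fallen genes and the sites in NT5E were chosen only after the result was seen; the scan itself was planned.

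In the adenosine pathway itself, 8 of 23 tested enzymes and transporters rose and 10 fell in ish, and 9 rose and 10 fell in ish2, with no list call (camera adjusted p = 0.535 and 0.932). ENPP1, which makes AMP from ATP, rose in both constructs (0.99 and 0.52), as did ENTPD6, a nucleoside diphosphatase (0.44 and 0.42). ALPL, a phosphatase that also makes adenosine from AMP, fell in both (-0.55 and -0.57), and so did the nucleoside transporter genes SLC29A1 (-0.31 and -0.94) and SLC29A4 (-0.95 and -0.64). PNP, which breaks down inosine, fell by 1.31 in ish and rose by 0.63 in ish2. Of the receptors, ADORA1 rose by 1.09 in ish and fell by 0.80 in ish2, and ADORA2A, ADORA3 and P2RX7 had at most 10, 3 and 5 counts in any library and were not tested. The receptor list had no call in ish2, where 3 of 9 rose and 3 fell (camera adjusted p = 0.997).

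Other groups changed member by member, without a list call at the main settings in the construct or constructs given for each. TNC, a matrix glycoprotein, rose in both (0.86 and 1.27), while COL4A2, of basement membranes, fell by 1.87 in ish (0.04 in ish2, not called). Matrix genes rose at 12 and fell at 21 of 36 in ish, and 16 and 14 in ish2 (camera adjusted p = 0.0739 and 0.932). The ish value ranged from 0.0283 to 0.41 over the camera alternatives, so the lack of a call depended on the setting. NOTCH3 fell by 0.55 in both, and 7 of 21 NOTCH genes rose and 11 fell in ish, 6 and 10 in ish2 (camera adjusted p = 0.22 and 0.324). IGF2 fell in both (-2.13 and -0.51) and FBXO32, a muscle atrophy ligase, rose in both (0.98 and 1.795), among PI3K, AKT and FOXO genes of which 12 rose and 10 fell in ish and 13 and 7 in ish2 (0.705 and 0.268). CTGF fell by 2.17 in ish and rose by 1.00 in ish2; the 21 YAP and TAZ targets had 9 up and 11 down, then 11 and 7 (0.718 and 0.527). The p53 targets had 7 up and 10 down of 23 in ish and 13 and 4 in ish2 (0.64 and 0.0957), with SESN1 up in both (1.73 and 0.38). HIST1H2AC and HIST1H2BK rose in both, and the 15 histone genes had 5 up and 2 down, then 5 and 1 (0.352 and 0.268). Epithelial markers had 4 of 5 down in ish and 4 up in ish2 (0.0935 and 0.0957, the latter 0.0329 to 0.486 over the camera alternatives), among them KRT18 (-2.17 and 0.58). Immune markers had 3 of 7 down, then 2 up and 1 down (0.439 and 0.527). Neural markers had 5 of 9 up and 2 down, then 3 and 4 (0.155 and 0.997), with the neurofilament INA up in both (1.74 and 0.67). In ish, 4 cAMP genes rose and 11 fell (camera adjusted p = 0.0935) and 6 unfolded protein response genes rose and 12 fell (0.0935). Over the camera alternatives these ranged from 0.0433 to 0.328 and from 0.0424 to 0.547, so the lack of a call depended on the setting. In ish2, 13 of 30 myogenic regulators rose and 12 fell (0.633), 11 of 33 ATF4 genes rose and 11 fell (0.932), 14 cholesterol genes rose and 6 fell (0.141, called without ish2 no-Dox replicate 3 at 0.0277; range over the camera alternatives 0.0277 to 0.802), 3 endothelial markers rose and 1 fell (0.543), and cytosolic (18 and 18 of 69; 0.675) and mitochondrial ribosomal proteins (26 and 20 of 72; 0.932) had no call. Median, mean and camera direction differed in sign in ish2 for the receptors (median 0.23, mean 0.143, camera down), the myogenic regulators (0.0687, -0.104, down), the matrix genes (0.0413, -0.0698, up), the ATF4 genes (0.0536, -0.0149, down), the NOTCH genes (-0.0618, 0.0156, down), the neural markers (-0.0914, 0.343, down), and the cytosolic (0.00561, -0.0343, down) and mitochondrial (0.0168, -0.0013, up) ribosomal proteins. They also differed in ish for the PI3K list (0.0468, -0.0442, up), in the mean effect for the unfolded protein response (0.0759, -0.0431, down), and in the difference for the histone genes (0.419, 0.397, down).

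In the scan of 3' UTR words, the 7-mer that went with the largest falls was ATCATGA in ish (median log2 fold change -0.224 in 1426 genes with it and 0.019 in the rest) and GAACGCA in ish2 (-0.191 in 215 genes and 0.019 in the rest). The 3 leading words of each construct overlap in 1 stretch of NT5E mRNA: ATCATGAAT on chromosome 6 from 85467070 to 85467078, in the coding part of exon 2, and TGAACGCAA from 85489586 to 85489594, in the coding part of exon 6. Single leading words also lie elsewhere in it: TCATGAA (exon 1) and ATCATGA (3' UTR) for ish, and TGAACGC (exon 1) for ish2. The mRNA holds 1.475% of all 9-mers, but leading words tend to overlap each other, so that share is not the chance of such a stretch. The hairpin sequences are not given in the sources used here, so whether these stretches are the target sites was not tested. Words that went with rises also passed the permuted range in ish2, namely TTATTTA (t = 6.03), TATTTAT (5.78) and GCACTTT (5.55) against 5.37. None of them occurs in NT5E mRNA on either strand, so passing the permutations does not by itself point to the hairpin. In ish the leading word for rises stayed within the range (4.53 against 5.63).

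A hypothesis from these data is that part of each response may be seed-matched silencing by the hairpin rather than loss of CD73. The leading words had t = -13.79 in ish and -9.62 in ish2, beyond every one of 100 permutations. Some words of rises in ish2 that NT5E does not hold passed them too. In the other construct t was -1.92 for the ish word and -1.27 for the ish2 word. Both lie within the permuted range, which spans the extremes of all words, so a weaker association could lie inside it. Genes with the ish2 word had a median log2 fold change of -0.109 in ish, against -0.008 without it. Those with the ish word had 0.054 in ish2, against 0.011. The drop in t argues against a property of the genes, not dependent on the construct, as the whole cause of either association. A smaller part of that kind is not excluded. Of the words scanned, the 2 leading ones alone do not account for every fall as direct targets: 33.82% of the genes that fell by at least 1 in ish held 1 of the 2 leading words, against 20.56% of the genes that changed less, and 16.46% against 3.3% in ish2. Sites of other words, and falls downstream of a silenced gene, were not tested.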
